A study of Mus musculus with 7 samples.

How the data were processed

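The series holds 7 droplet single-cell RNA libraries of mouse brain made with the 10x Chromium 3' kit. Per the labels, P2, P7, P15 and P60 cortex came from the region dorsal to the lateral ventricles, P60 grey matter from above the cortical white matter, P60 white matter from directly above the ventricles, and P7 SVZ from the dorsal and lateral ventricular-subventricular zone. The P7 SVZ mice were C57BL/6 and the others CD1. The labels call P2, P7 and P15 early postnatal and P60 adult, which gave 4 early and 3 adult libraries. Nothing in the labels says that the libraries come from separate animals, so p-values here measure the spread between these libraries.

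The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 3.0.2 per the file headers and build mm10 per the submitters' processing notes. The other deposited files hold only names (barcodes, and gene identifiers with symbols). Whole numbers, unequal library totals and equal row order in all 7 matrices were checked. The gene annotation release and whether reads were counted by strand are not given in the sources used here. Of the 31053 genes, 30934 matched GENCODE M21, from which positions on mm10 and gene types were taken.

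Libraries held 3584, 4364, 6379, 3456, 3365, 2472 and 2127 barcodes in the order P2 cortex, P7 cortex, P7 SVZ, P15 cortex, P60 cortex, grey matter and white matter. Their totals ran from 10074763 to 45668007 UMIs. Barcodes with under 500 detected genes (1304) or over 10% mitochondrial UMIs (3441) were left out, as were 293 doublet calls (scrublet in scanpy 1.11.5, expected rate 0.06, per library), which left 20709 cells. Median UMIs per kept cell were 9537, 6845, 8291.5, 5605, 2791, 6113 and 4439. Most loss was in P7 SVZ, where 2132 barcodes (33.4%) passed the mitochondrial limit.

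All kept cells were scaled to 10000 UMIs, logged and reduced to 30 principal components of 2000 variable genes. Leiden clustering (15 neighbours, resolution 1.5, seed 1) gave 47 clusters. Each was named by marker lists when at least 3 markers of a class were raised at least 2-fold and detected in at least 10% of cells, and when its 10 leading genes held no more markers of another class. Clusters with a median UMI count under 1/3 of the library level and no own marker among the 10 leading genes stayed unnamed. This left 6 clusters (762 cells) unnamed: 0.523, 0.910, 8.73, 2.50, 0.654, 15.6 and 0.355% of cells in library order. Classes are written as "-like" because they rest on RNA markers alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

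Counts of each class were summed per library where it had at least 20 cells (15 for cycling sums). Sums of oligodendrocyte precursor cell (OPC)-like cells held 167, 331, 535, 491, 108, 121 and 89 cells and 1096610.0, 2607889, 4442530.0, 3082780.0, 410962, 604013 and 371922 UMIs in library order. The 3-count floor of these sums lay between 0.675 and 8.07 CPM (UMIs of a gene scaled by the total of its sum). Stages were compared with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The same test ran on committed precursor (COP)-like, astrocyte-like, neuroblast-like and microglia-like sums. OPC-like cells of 5 libraries were also compared by cycling call, with the library as a block and without the S and G2M list genes, which define the calls.

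A cycling call meant at least 3 UMIs of the S and G2M lists after thinning each cell to 2000 UMIs, and a non-cycling call 0 such UMIs. Shallower cells were left out of that share. Shares were compared with an exact permutation test over the 35 splits of 4 against 3 libraries, whose smallest p is 0.0571, so no share could pass 0.05. Pairs with 1 library per side (white against grey matter at P60, SVZ against cortex at P7) and the 4 cortex ages got no test: CPM with exact Poisson 95% intervals and ratios with exact conditional intervals cover counting error only.

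The 16 gene lists were S phase, G2M phase, early progenitor, OPC identity, differentiation onset, myelin, cholesterol synthesis, glutamate and GABA receptors, voltage-gated ion channels, extracellular matrix, antigen presentation and interferon, dissociation-response genes, imprinted and growth genes, cyclin-dependent kinase inhibitors, dorsal and ventral patterning, and RNA of abundant non-OPC classes. Each was tested by camera (limma 3.58.1, inter-gene correlation 0.01, and again with an estimated correlation) over the members that passed the filter. In the pairs a list's median ratio was placed among 10000 random lists matched for expression. Members were also adjusted over their list alone.

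The design, the lists, the class markers, the genes always given and the rule for named genes were fixed before the data were examined, as were most alternatives. Chosen later were the scoring rule for cluster names, the estimated list correlation, the stage tests of lists under other settings and the other-class alternatives. So were the test of genes past the 0.5 limit, leaving out 2 libraries together, and the same-direction share of uncalled genes in other classes. Named genes were the called ones with the largest fold change and at least 50 CPM in the higher group: 12 per direction between stages, 10 for the cycling test and the pairs, 5 in other classes. Between stages and in other classes the libraries of the 2 stages also had not to overlap. In the pairs, genes were ordered by the interval bound nearer 1. Except in the cycling test, a named gene reached at least 0.5 times the level of the library's other cells in most libraries of the higher group, as a limit on background RNA. Gene models without a name, mitochondrial, ribosomal protein, haemoglobin and Y-linked genes and Xist were not named, unless a count of 5 or fewer was spelled out. Some genes picked by these rules are not reported here. From each list up to 4 members may be named by adjusted p or interval bound.

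Alternatives were RLE size factors, DESeq2 1.42.0 (Wald test), no filter on low counts, doublets kept, at least 1000 genes, a mitochondrial limit of 20%, clusters made per library, a gate on Pdgfra plus other markers, equal cell numbers, only genes past the 0.5 limit, an estimated correlation for the lists, cells with 0 cycle-list UMIs, other cycling thresholds and depths, 0.5 and 2 times the resolution, each library left out in turn, and P7 SVZ and P60 grey matter left out together. Choroid plexus and erythroid clusters were not found, and unnamed cells entered no test.

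The tests were tested on simulated data with 200 changed genes, drawn as negative binomial counts from each gene's mean level and fitted dispersion. Unchanged genes had the same mean level in every simulated library, without shared differences of age, region or strain. The rates below therefore need not hold for the real calls. Between stages (4 against 3 libraries, 9373 genes), 10.2% of genes changed 2-fold upward and 4.44% of those halved were called, against 100% at 4-fold and 100% at 8-fold, and 8.55% of calls were false. In the cycling test (5 libraries, 8242 genes), 96% at 2-fold, 78% of halved genes and 100% at 4-fold and 8-fold were called, and 2.60% of calls were false. The 95% intervals covered the true value in 96.5% (binomial), 95.6% (Poisson) and 96.5% (ratio) of draws.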

Results

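The 7 libraries gave 20709 cells in 47 clusters, of which 1842 cells from 4 clusters carried markers of oligodendrocyte precursor cells (OPCs). OPC-like cells made up 5.14% (95% interval 4.41 to 5.96) of P2 cortex, 8.14% (7.32 to 9.02) of P7 cortex, 14.6% (13.5 to 15.8) of P7 SVZ and 17.3% (15.9 to 18.8) of P15 cortex. At P60 they made up 3.53% (2.90 to 4.25) of cortex, 6.50% (5.42 to 7.72) of grey matter and 4.51% (3.64 to 5.52) of white matter. Committed precursor (COP)-like cells reached 14.4% at P15 and 0.644 to 4.37% in the other 6 libraries. Mature oligodendrocyte-like cells made up 45.1% of P60 white matter, 11.6% of P60 cortex, 1.67% of P60 grey matter and 7.16% of P15 cortex.

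Other classes set the libraries apart as well. Excitatory neuron-like cells were 55.1% of P2 cortex, and astrocyte-like cells 33.2% of P7 cortex, 26.1% of P15 cortex and 34.7% of P60 cortex. Microglia-like cells were 0.739% of P2 cortex, 18.8% of P15 cortex, 35.9% of P60 cortex and 60.5% of P60 grey matter. Neuroblast-like cells were 23.6% of P7 SVZ and 14.8% of P60 white matter, and striatal neuron-like cells 13.9% of P7 SVZ. A microglia-like cluster led by Atf3, Klf4 and Junb held 322 of its 524 cells in P60 grey matter, and a microglia-like cluster led by Il1a, Cd83 and Tnf held 742 of 751 there.

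**Figure D1:**
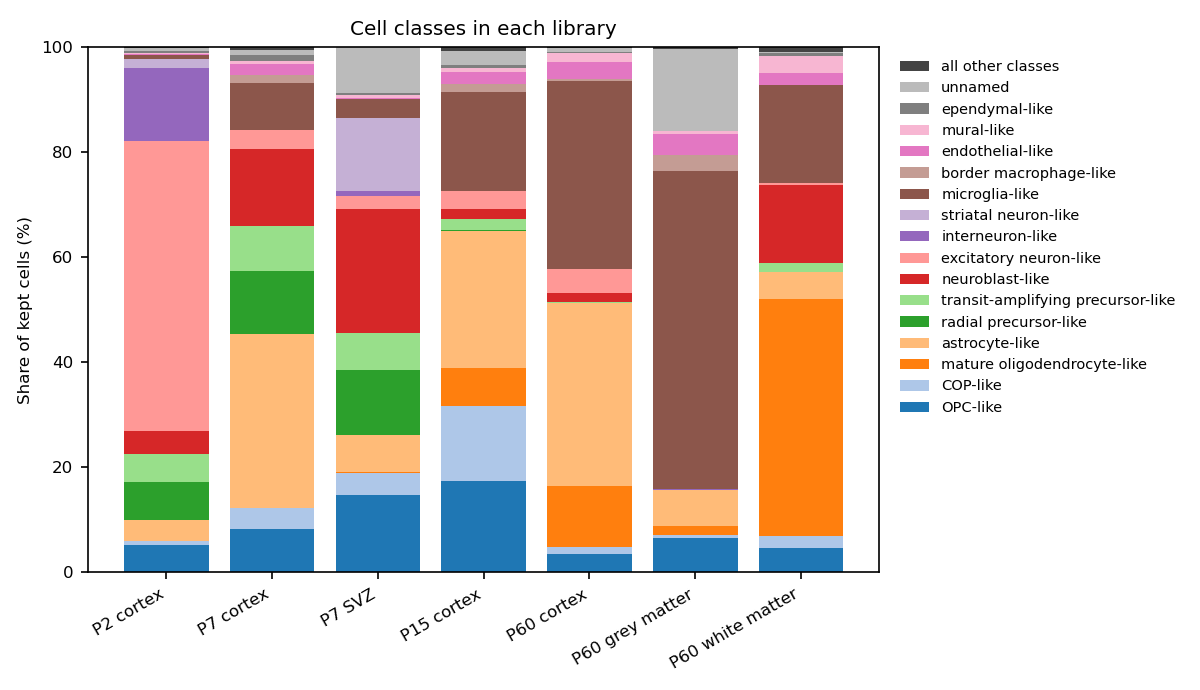
Cell classes in percent of the kept cells of each library. OPC-like cells made up 17.3% of P15 cortex and 3.53% of P60 cortex.

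Within the OPC-like class the libraries fell into different clusters. Cluster 27, led by Pdgfra, Lhfpl3 and Cspg4, held 78.9% of the P7 SVZ cells, and cluster 14, led by C1ql1 and Dll3, held 61.1% of the P2 and 53.2% of the P7 cortex cells. Cluster 13, led by Pdgfra, C1ql1 and Mmp15, held 61.9% at P15 and 88.0, 95.9 and 77.5% in P60 cortex, grey matter and white matter. Cluster 9, led by the mitotic genes Ube2c and Birc5, held 11.4, 15.4, 19.4 and 8.76% in the early libraries and 2.78, 0.826 and 2.25% in the adult ones. After thinning to equal depth, Pdgfra, the receptor that OPCs depend on for growth, was found in 68.1, 72.6, 73.0 and 85.7% of early and 91.3, 82.7 and 88.5% of adult OPC-like cells. In microglia-like cells, which should lack it, it was found in at most 0.862%, and in mature oligodendrocyte-like cells in at most 1.98% (P15 cortex). Pdgfra is one of the markers that named the class, so its detection is no separate check of the class.

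The OPC-like share averaged 11.3 ± 5.62% (SD, n = 4) in early and 4.85 ± 1.51% (n = 3) in adult libraries, a difference of -6.45 points with an exact permutation p of 0.114 (n = 7). Mature oligodendrocyte-like cells made up 0 of 190 lineage cells at P2 (up to 1.92%), 0.402% in P7 cortex, 0.144% in P7 SVZ and 18.4% (16.2 to 20.8) at P15. Their share was 70.4% in P60 cortex, 18.9% in grey matter and 86.7% in white matter. The mean was 4.74 ± 9.11% (n = 4) against 58.7 ± 35.4% (n = 3). The share was higher in 3 of 3 adult libraries than in any early one, with an exact permutation p of 0.0571 (n = 7), the smallest this design can give. The interval of P60 grey matter (13.2 to 25.7) held the P15 share, so these 2 libraries were not told apart.

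Cycling calls were made in 28.2% (21.5 to 35.8) of P2, 33.5% (28.4 to 39.0) of P7 cortex, 35.8% (31.8 to 40.1) of P7 SVZ and 22.4% (18.8 to 26.4) of P15 OPC-like cells. At P60 the shares were 8.70% (3.83 to 16.4) in cortex, 14.4% (8.30 to 22.7) in grey matter and 12.8% (6.32 to 22.3) in white matter. Mki67, which marks cells in the cycle, stood at 62.0, 89.3, 156 and 64.6 CPM in the early and 34.1, 16.6 and 24.2 CPM in the adult sums. The DNA topoisomerase gene Top2a stood at 138, 201, 289 and 135 against 58.4, 33.1 and 8.07 CPM. The mean cycling share was 30.004 ± 5.99% (n = 4) against 11.98 ± 2.95% (n = 3). It was lower in 3 of 3 adult libraries, a difference of -18.0 points with an exact permutation p of 0.0571 (n = 7), the smallest this design can give. Mature oligodendrocyte-like cells, which do not divide, still had such calls in 1.49% (P15), 9.66% (P60 cortex), 19.4% (grey matter) and 9.69% (white matter) of cells. In each adult library this rate lay within the interval of the OPC-like share, so adult calls alone were not shown to mark dividing cells. Such calls reached 0.938, 2.41 and 1.25% of astrocyte-like cells in P60 cortex, grey and white matter. In microglia-like cells they reached 2.68, 21.2 and 6.15%. Mki67 stood at 4.48, 3.47 and 4.53 CPM in mature oligodendrocyte-like cells of these libraries, below the OPC-like sums. Top2a stood at 0.560, 0 and 0.412 CPM there. Median depths of mature oligodendrocyte-like cells were 23328, 4732, 8252 and 4961 UMIs, and OPC-like median depths 6400.0, 7651, 7941 and 5598 UMIs early and 3716, 5348 and 4108 in the adult. Without thinning the shares were 49.1, 68.6, 66.5 and 39.1% against 18.5, 39.7 and 28.1%. The thinned shares left out 4, 6, 5 and 9 early and 16, 17 and 11 adult cells as too shallow.

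**Figure D2:**
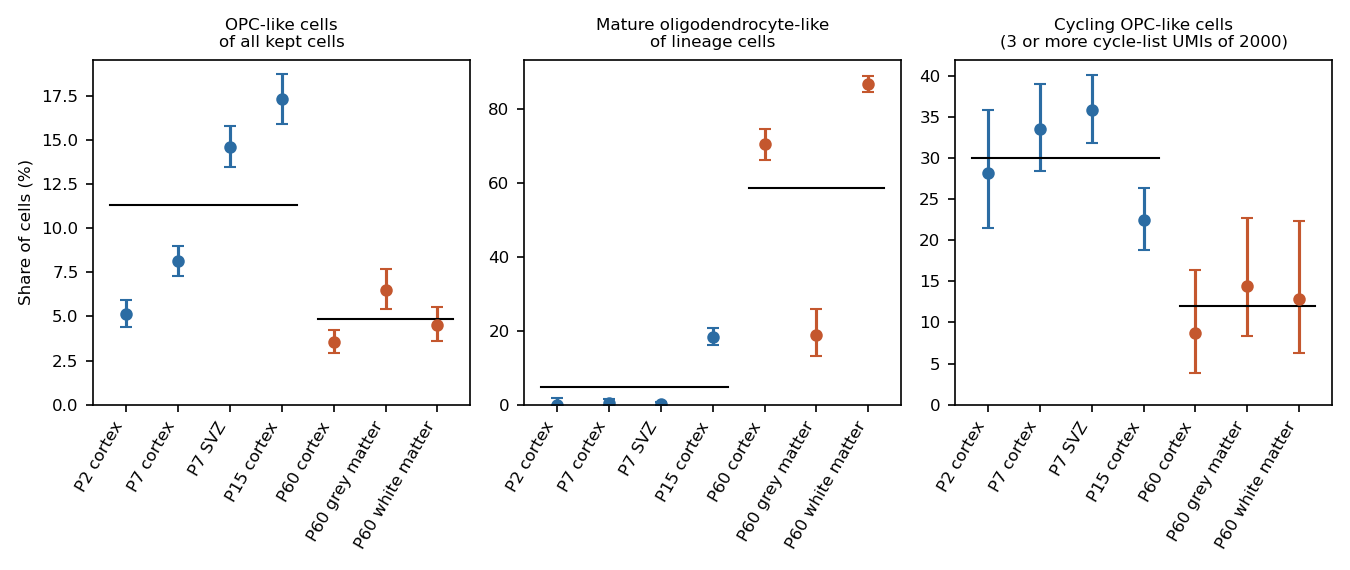
Shares per library with exact 95% intervals; black lines are the group means. The mature share of the lineage was 18.4% in P15 cortex and 86.7% in P60 white matter.

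Between the stages, single genes of a connexin, of the matrix and of lipid transport were higher in adult OPC-like cells, and many cell cycle genes lower. Gjc3, a connexin of the oligodendrocyte lineage (ENSMUSG00000056966, chromosome 5, 137953461 to 137963098, mm10), rose from 20.7 ± 23.1 to 391 ± 49.7 CPM, a log2 fold change of 4.03 ± 0.51 (SE) with an adjusted p of 0.00290. Hapln1, which links hyaluronan to proteoglycans (ENSMUSG00000021613, chromosome 13, 89539796 to 89611652), rose from 5.02 ± 7.36 to 82.6 ± 8.71 CPM (3.75 ± 0.66, adjusted p 0.00925). The secreted matrix gene Sparcl1 (ENSMUSG00000029309, chromosome 5, 104079111 to 104113733) rose from 142 ± 86.9 to 1186 ± 615 CPM (2.89 ± 0.47, adjusted p 0.00670). Apoe, a lipid carrier gene (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), rose from 810 ± 467 to 5773 ± 3528 CPM (2.67 ± 0.48, adjusted p 0.00977). Lower in the adult was Rbm3, a cold-induced RNA-binding protein gene (ENSMUSG00000031167, chromosome X, 8138975 to 8145880), at 574 ± 152 against 109.6 ± 24.6 CPM (-2.62 ± 0.31, adjusted p 0.00186). All values are means of 4 early and 3 adult sums by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. As the naming rule required, each named gene was higher or lower in 3 of 3 adult libraries than in any early one. This separation is therefore no separate evidence.

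Further genes that rose were Ifi27 (3.71 ± 0.50; 19.9 to 307.5 CPM), Gpld1 (3.32 ± 0.66; 8.37 to 96.9), Tmem59l (3.02 ± 0.48; 14.02 to 132) and the homeobox gene Meox1 (2.91 ± 0.72; 21.05 to 183). With them rose Gstt1 (2.82 ± 0.36; 6.48 to 53.6), Susd5 (2.80 ± 0.55), C1ql2 (2.79 ± 0.41; 13.96 to 111) and Faim2 (2.72 ± 0.45). Further genes that fell were the replication factor Pclaf (-3.31 ± 0.47; 185 to 23.4 CPM), the transcription factor Npas1 (-3.03 ± 0.50; 85.2 to 11.6) and Cks1b (-2.45 ± 0.29). The mitotic genes Top2a (-2.72 ± 0.45; 191 to 33.2), Birc5 (-2.59 ± 0.48), Ube2c (-2.55 ± 0.60), Cdca3 (-2.45 ± 0.43), Nusap1 (-2.42 ± 0.39) and Prc1 (-2.39 ± 0.46) fell too. The histone gene Hist1h2ap (-3.73 ± 0.53; 173 to 14.8 CPM) has near copies, so its reads are uncertain. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p of these genes ran from 0.00186 (Cks1b) to 0.0318 (Meox1). Of the genes named so far, Gjc3, Ifi27, Gstt1, Rbm3, Pclaf and Cks1b were still called without P60 grey matter and the others were not. With 1 library left out the log2 fold changes ranged most widely for Ube2c (-4.59 to -2.002), Hapln1 (3.28 to 5.40), Meox1 (2.12 to 4.21), Gpld1 (2.85 to 4.72) and Birc5 (-3.74 to -2.16).

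Markers of the class itself did not pass the test: Pdgfra had 809 ± 164 CPM early and 1270.1 ± 223 in the adult (log2 fold change 0.46 ± 0.23, adjusted p 0.258 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Not called either were Cspg4 0.51 ± 0.21 (0.162), Olig1 0.46 ± 0.34 (0.456), Olig2 0.26 ± 0.31 (0.677) and Sox10 0.50 ± 0.21 (0.176). Pdgfra, Cspg4 and Sox10 did not overlap between the stages, while Olig1 and Olig2 did. Only 10.2% of simulated 2-fold rises were called, so a rise of this size was not excluded. The differentiation marker Gpr17 (0.38 ± 0.27, 0.452) and the myelin gene Mbp (-0.09 ± 0.66, 0.958) did not pass. Mbp in OPC-like cells lay near its level in microglia-like cells. Mki67 fell (-2.15 ± 0.42, adjusted p 0.0140; 93.0 to 24.9 CPM), and Egfr had too few UMIs to be tested.

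In all, 308 genes were higher and 345 lower in the adult among 9812 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 4 and 3 libraries). An unadjusted p under 0.05 was found for 2188, and 625 of the 653 called genes did not overlap between stages (2269 of the tested genes, where chance gives 5.71%). The counts depended on single libraries: they were 87 and 144 without P2 cortex, 107 and 161 without P7 cortex and 614 and 591 without P15 cortex. They were 82 and 82 without P60 cortex, 8 and 7 without P60 grey matter and 125 and 117 without P60 white matter. Y-linked genes parted the stages: Eif2s3y, Ddx3y, Uty and Kdm5d, all Y-linked and among the lower genes, were at 0 CPM in the adult OPC-like sums. Xist stood at 333, 823, 642 and 1018 CPM in the early against 3578, 2049.5 and 2540.1 CPM in the adult libraries.

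**Figure D3:**
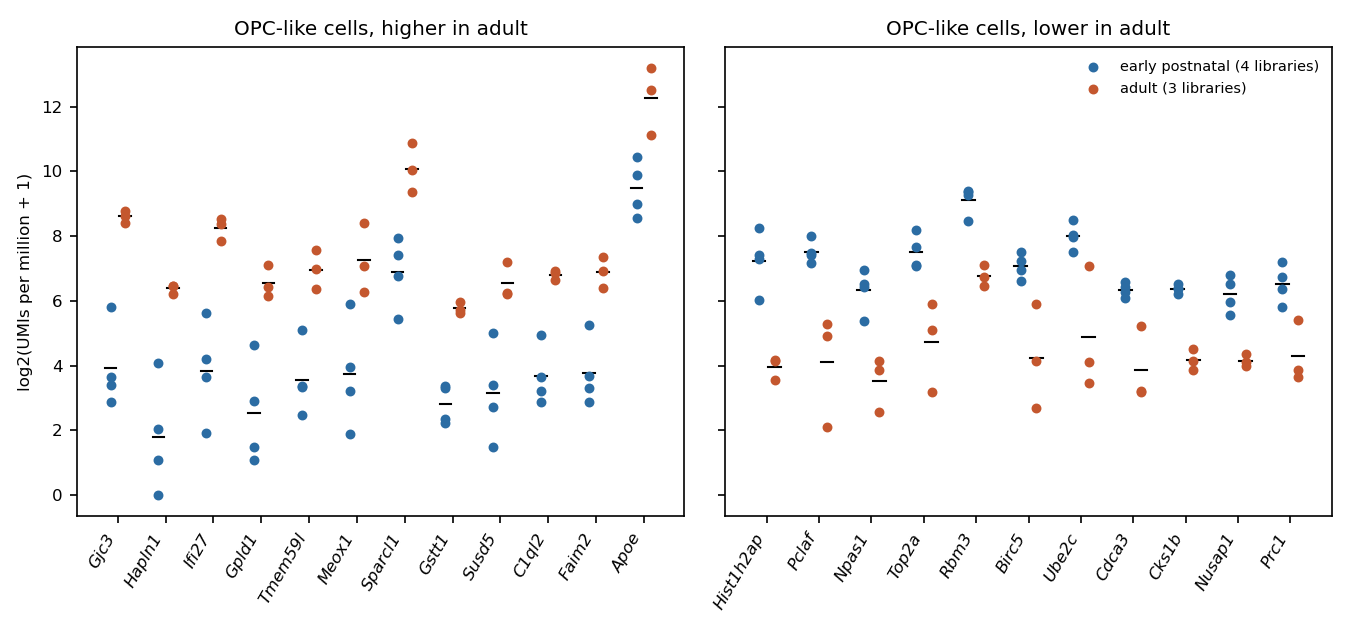
Named genes in OPC-like sums, log2 of CPM plus 1 per library; black marks are means. Gjc3 stood at 55.1 CPM in P15 cortex and 440.4 CPM in P60 cortex.

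Many cell cycle genes were lower in the adult. Of 33 tested G2M genes 21 were lower, 0 higher and 12 not called (32 lower when adjusted over the list alone). Examples are Kif23 (-2.89 ± 0.46), Hmgb2 (-1.51 ± 0.24; 495 to 200.4 CPM), Nusap1 and Top2a. Of 24 S phase genes 12 were lower, 0 higher and 12 not called (20 lower over the list alone), among them Rrm2 (-2.35 ± 0.38), Fen1 (-1.98 ± 0.35) and Gins2 (-1.93 ± 0.39). Median log2 fold changes were -2.23 and -1.57, with camera adjusted p of 4.3e-33 and 7.4e-14. With an estimated correlation both adjusted p were 0.229. The G2M count was 13 without P7 cortex, 0 without P60 grey matter and 9 without P60 white matter. The S phase count was 4 without P2 cortex, 6 without P7 cortex, 3 without P60 cortex, 0 without P60 grey matter and 4 without P60 white matter. Medians without P60 cortex, grey matter and white matter were -3.09, -1.86 and -2.07 for G2M and -1.48, -1.60 and -1.77 for S phase genes.

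Some genes of sterol synthesis and of early progenitors were also lower. Of 21 cholesterol genes 12 fell, 0 rose and 9 were not called (14 lower over the list alone). Among them were Hmgcs1 (-1.89 ± 0.41; 327 to 102 CPM), Sqle (-1.85 ± 0.41) and Fdps (-1.32 ± 0.32). The cholesterol median was -1.43, with a camera adjusted p of 1.1e-10 and an adjusted p of 0.239 with an estimated correlation. Of 15 early progenitor genes 4 fell, 0 rose and 11 were not called (1 higher and 5 lower over the list alone). Those that fell were Fabp7, a lipid-binding gene of neural precursors (-1.72 ± 0.33; 3529 to 1255 CPM), the Notch effector Hes5 (-1.66 ± 0.38; 714 to 265), Nes (-2.44 ± 0.63) and Dll3 (-1.47 ± 0.39). The early progenitor median was -0.25, with a camera adjusted p of 0.00826 and an adjusted p of 0.239 with an estimated correlation. Without P2 cortex 1 cholesterol and 1 early progenitor gene were called, and without P7 cortex 2 and 2. Without P7 SVZ 7 cholesterol genes were called, and without P60 cortex, grey matter or white matter 0 and 0. Medians without these 3 in turn were -1.33, -1.33 and -1.65 for cholesterol and -0.51, -0.66 and -0.32 for early progenitor genes.

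Of the matrix and OPC identity lists 3 and 1 genes were called with all libraries. In the extracellular matrix list of 16, Sparcl1 and Hapln1 rose, Col9a3 fell (-1.24 ± 0.24; 188 to 90.7 CPM) and 13 were not called (8 higher and 1 lower over the list alone). Its median was 0.44, with a camera adjusted p of 0.00321 and an adjusted p of 0.239 with an estimated correlation. In the OPC identity list of 17, Megf11 rose (1.03 ± 0.24), 0 fell and 16 were not called (1 higher and 0 lower over the list alone). Its median was 0.46, with a camera adjusted p of 0.000638 and an adjusted p of 0.273 with an estimated correlation. Without P15 cortex 6 matrix genes were higher and 1 lower, and without P60 grey matter 0 and 1. The OPC identity count was 4 without P15 cortex, 2 without P7 SVZ and 0 without any 1 of the other 5 libraries.

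In the voltage-gated ion channel list of 20, 2 genes rose, 0 fell and 18 were not called (2 and 0 over the list alone). Among those that rose was Kcnj16 (2.24 ± 0.35, 10.8 to 61.2 CPM), an inward rectifier gene that is not voltage-gated. The list also held Kcnj10, another inward rectifier gene, and Kcnk2, a leak channel gene. The list's median was 0.22, with a camera adjusted p of 0.0225 and an adjusted p of 0.442 with an estimated correlation. The channel count was 4 without P15 cortex, 1 without P60 cortex or white matter and 0 without P60 grey matter. Of 19 glutamate and GABA receptor genes 0 were higher, 0 lower and 19 not called by edgeR's quasi-likelihood test, and 0 over the list alone. Their median was 0.15, with a camera adjusted p of 0.485 and an adjusted p of 0.718 with an estimated correlation. Without P15 cortex 1 receptor gene was higher.

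Differentiation genes were mostly not called. In the differentiation onset list of 13, the kinase gene Fyn fell (-0.999 ± 0.25; 212 to 122 CPM), 0 rose and 12 were not called (1 higher and 1 lower over the list alone). Its median was 0.13, with a camera adjusted p of 0.533 and an adjusted p of 0.741 with an estimated correlation. In the myelin list of 12, Gjc3 rose, 0 fell and 11 were not called (1 and 0 over the list alone). Its median was 0.23, with a camera adjusted p of 0.00826 and an adjusted p of 0.442 with an estimated correlation. Without P15 cortex 3 of 9 myelin genes were higher, with a median of 0.55, and 1 differentiation onset gene was higher and 1 lower. Without P2 cortex or any 1 of the 3 adult libraries 0 differentiation onset genes were called.

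Of 7 patterning genes 0 were higher, 0 lower and 7 not called, and 0 over the list alone. Their median was -0.10, with a camera adjusted p of 0.425 and an adjusted p of 0.464 with an estimated correlation. Of 10 imprinted and growth genes Ndn (-1.36 ± 0.30; 216 to 95.7 CPM) and Grb10 (21.6 to 0.896 CPM) fell, Impact rose (0.94 ± 0.24) and 7 were not called (1 higher and 3 lower over the list alone). Their median was -0.25, with a camera adjusted p of 0.123 and an adjusted p of 0.442 with an estimated correlation. Imprinted genes higher and lower were 2 and 3 without P15 cortex, 0 and 1 without P7 cortex, and 0 and 0 without P2 cortex or any 1 of the 3 adult libraries.

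Among 6 cyclin-dependent kinase inhibitor genes Cdkn1a (3.71 ± 0.38; 2.96 to 46.4 CPM) and Cdkn2b (0.614 to 13.04 CPM) rose, 0 fell and 4 were not called (2 and 0 over the list alone). The list's median was -0.10, its mean 1.07 and its camera direction upward, with an adjusted p of 0.0138 and an adjusted p of 0.229 with an estimated correlation. Cdkn1a lay under 0.5 times the level of the other cells in most adult libraries, as did Hspa1a, Dusp1, Dnajb1, C1qa and C1qb below. Dissociation-response genes, which cell handling can induce, rose in 4 of 18, fell in 0 and were not called in 14 (9 higher over the list alone). Those that rose were Hspa1a (4.92 ± 0.67; 6.43 ± 6.30 to 218 ± 190 CPM), Dusp1 (2.15 ± 0.47), Nr4a1 (1.84 ± 0.47) and Dnajb1 (1.29 ± 0.34). Their median was 1.46, with a camera adjusted p of 6.2e-07 and an adjusted p of 0.302 with an estimated correlation. The dissociation-response count was 12 of 18 without P7 SVZ, 6 of 22 without P60 cortex, 2 without P2 or P7 cortex and 1 without P60 grey matter. The kinase inhibitor count was 1 without P7 cortex, P7 SVZ, P15 cortex or P60 grey matter.

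Of 7 antigen presentation and interferon genes Tap2 (1.97 ± 0.40; 7.26 to 31.6 CPM) and Tapbp (1.44 ± 0.38) rose, 0 fell and 5 were not called (3 higher over the list alone). Their median was 0.98, with a camera adjusted p of 0.00253 and an adjusted p of 0.302 with an estimated correlation. Of 4 tested genes of abundant non-OPC classes 3 rose, 0 fell and 1 was not called (4 higher over the list alone). Those that rose were the microglial complement genes C1qb (3.84 ± 0.68; 4.796 to 81.0 CPM) and C1qa (3.53 ± 0.74; 8.50 to 113) and the astrocyte transporter gene Slc1a2 (1.21 ± 0.32; 122 to 323). The median was 2.37, with a camera adjusted p of 6.1e-05 and an adjusted p of 0.229 with an estimated correlation. The antigen count was 1 without P2 cortex, P7 cortex, P60 cortex or P60 white matter, 3 without P15 cortex and 0 without P60 grey matter. The non-OPC count was 2 without P2 cortex, P7 cortex or P60 cortex and 0 without P60 grey matter. Without P60 grey matter, where 8 and 7 genes were called in all, the median was 0.37 for dissociation-response, 0.45 for antigen and -1.86 for G2M genes, over the members tested there. Altogether 12 of the 16 lists passed camera at a correlation of 0.01 and 0 with an estimated correlation.

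**Figure D4:**
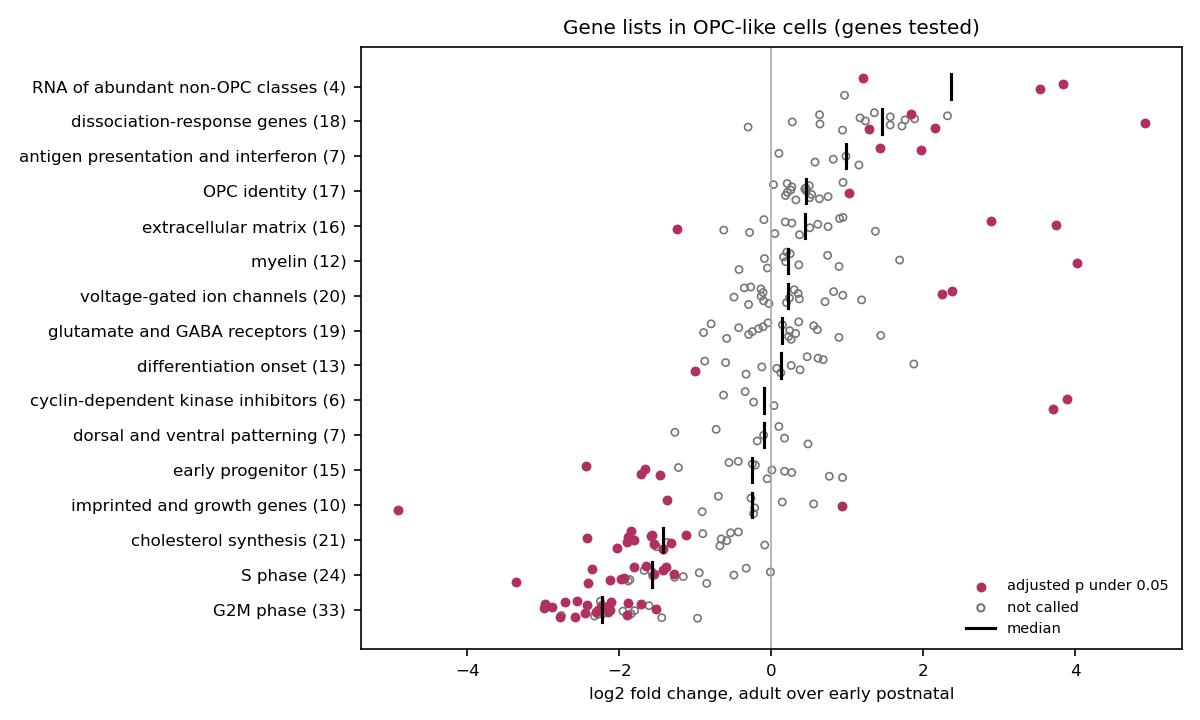
Log2 fold changes, adult over early, of list members; filled points are genes with an adjusted p under 0.05 and lines are medians. The median was -2.23 for G2M genes and 0.46 for OPC identity genes.

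Along the 4 cortex libraries, with 1 library per age and no test, Pdgfra stood at 636 (589 to 685), 773 (739 to 807), 1031 (996 to 1068) and 1499 (1383 to 1622) CPM at P2, P7, P15 and P60. Gjc3 stood at 6.38, 9.59, 55.1 and 440.4 CPM, Apoe at 377, 952, 1405 and 5799, and Hapln1 at 0 (up to 3.36), 3.07, 15.9 and 87.6. Summed over each list, early progenitor genes stood at 7318, 5980.3, 4039 and 3205 CPM and OPC identity genes at 10333, 11298, 16993 and 19909. Receptors stood at 1208, 1381, 1788 and 2115, ion channels at 567, 648, 909 and 1158, and matrix genes at 4735, 5348, 7143 and 9733. In P60 grey and white matter receptors stood at 1546 and 1651 CPM, below P15 cortex, and ion channels at 894 and 1073. Myelin genes (657, 1075, 2248 and 1684) were highest at P15, and differentiation onset genes stood at 1133, 1393, 2215 and 2207. G2M genes (1989, 3694, 2194 and 1353), S phase genes (785, 926, 697 and 338) and cholesterol genes (2071, 2856, 1099.98 and 745) were highest at P7. Intervals cover counting error only, and age and library cannot be told apart.

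OPC-like cells with cycling calls differed from those with non-cycling calls in the same libraries beyond the S and G2M lists, which were left out of the test. The calls rest on cycle genes, so higher levels of other cycle genes follow in part from that choice. The spindle gene Aspm had 422 UMIs (79.7 ± 28.8 CPM, n = 5) in cycling and 0 in non-cycling sums. Pooled over the libraries it stood at 97.6 CPM in cycling cells, at least 125-fold over the group floor of 0.783 CPM. By pooled values the thymidine kinase gene Tk1 was likewise at least 82.7-fold, the kinesin gene Kif15 at least 89.2-fold and Mxd3 at least 74.7-fold higher. Pbk (log2 fold change 7.42 ± 0.23, adjusted p 1.4e-39 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), the spindle midzone gene Prc1 (7.10 ± 0.22), the kinetochore gene Spc25 (6.84 ± 0.26) and Pimreg (6.70 ± 0.32; 3 UMIs in non-cycling sums) were higher in 5 of 5 libraries. Knl1 (7.85 ± 0.37) and Esco2 (7.54 ± 0.41), each with 1 UMI in non-cycling sums, were too. Lower in cycling cells of 5 of 5 libraries were Tmem179 (-1.14 ± 0.13; 153 to 75.2 CPM), Pik3ip1 (-1.14 ± 0.18), Tcp11l2 (-1.09 ± 0.18), Prss23 (-1.07 ± 0.20), Pcp4 (-1.07 ± 0.11; 384 to 209) and Idnk (-1.04 ± 0.17).

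In 4 of 5 libraries the antioxidant gene Gsta4 (-1.24 ± 0.26), Zfp365 (-1.09 ± 0.17), Gjc3 (-1.06 ± 0.22; 88.9 to 57.5 CPM) and the peptide gene Npy (-1.04 ± 0.22) were lower. Altogether 930 genes were higher and 683 lower among 8322 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a library block (n = 5 libraries). An unadjusted p under 0.05 was found for 2489. The counts were 603 and 363 without P7 SVZ, 442 and 157 with DESeq2, 543 and 426 at 2 or more UMIs, 208 and 105 on thinned sums and 218 and 6 without the block. At 2 or more UMIs P60 cortex (17 called cells) and white matter (20) also reached the minimum of 15, and 6044 genes were tested. In the main test P60 cortex (8 cycling cells) and white matter (10) were too small to enter, so adult cells came from grey matter alone. There 19.4% of non-dividing mature oligodendrocyte-like cells also had cycling calls, so its 15 called OPC-like cells were not shown to divide. Without grey matter 1064 genes were higher and 734 lower.

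Some genes of the later lineage were lower in cycling cells. Differentiation onset genes fell in 5 of 12, rose in 0 and were not called in 7: Gpr17 (-0.62 ± 0.08; 533 to 333 CPM), Neu4 (-0.93 ± 0.13), Bcas1 (-0.61 ± 0.09), Itpr2 and Bmp4. List-alone counts were 0 higher and 7 lower, and the adjusted p with an estimated correlation was 0.156. Myelin genes fell in 4 of 9 (Sirt2 -0.58 ± 0.08, Cnp -0.43 ± 0.09, Gjc3 and Fa2h), rose in 1 (Cldn11, 0.98 ± 0.22) and were not called in 4. List-alone counts were 1 and 6, with an adjusted p of 0.202 with an estimated correlation. OPC identity genes fell in 7 of 17, rose in 0 and were not called in 10, among them C1ql1 (-0.68 ± 0.08; 1473 to 892 CPM), Sox8, Sox6 and Pcdh15. Adjusted alone, 0 and 10 were called, with an adjusted p of 0.243 with an estimated correlation. Matrix genes fell in 7 of 12, rose in 0 and were not called in 5, with Tnr (-0.54 ± 0.09), Bcan (-0.34 ± 0.08), Sparcl1 (-0.43 ± 0.11) and Timp4 (-0.33 ± 0.09) as examples. Adjusted alone, 0 and 8 were called, with an adjusted p of 0.239 with an estimated correlation.

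Early progenitor genes went both ways. Of 15, 3 rose, among them Sox11 (0.65 ± 0.10) and Nes (0.74 ± 0.24), 4 fell (Hes5 -0.59 ± 0.10, Sox4, Hes6 and Dll3) and 8 were not called. List-alone counts were 3 and 4, with an adjusted p of 0.654 with an estimated correlation. Of 4 cyclin-dependent kinase inhibitor genes Cdkn2c (3.28 ± 0.16; 13.03 to 123 CPM) and Cdkn2d (1.37 ± 0.12) rose, Cdkn1c fell (-0.96 ± 0.20) and 1 was not called. Adjusted alone, 3 and 1 were called, with an adjusted p of 0.243 with an estimated correlation. The patterning genes Pax6 (1.85 ± 0.28) and Lhx2 (0.76 ± 0.17) rose, 0 fell and 4 of 6 were not called. List-alone counts were 2 and 0, with an adjusted p of 0.239 with an estimated correlation. Cholesterol genes rose in 5 of 21, among them Acat2 (0.65 ± 0.11), Fdft1 (0.47 ± 0.13), Fdps (0.34 ± 0.09) and Sc5d, fell in 0 and were not called in 16. List-alone counts were 5 and 0, with an adjusted p of 0.644 with an estimated correlation.

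Imprinted and growth genes fell in 3 of 10 (Meg3 -0.76 ± 0.10, Cdkn1c and Igf2bp3), rose in 0 and were not called in 7 (0 and 3 over the list alone; adjusted p 0.239 with an estimated correlation). In the receptor list Grik1 rose (0.76 ± 0.19), Gabbr1 (-0.33 ± 0.10) and Gria2 (-0.22 ± 0.08) fell and 15 of 18 were not called. Adjusted alone, 1 and 1 were called, with an adjusted p of 0.3402 with an estimated correlation. The sodium channel gene Scn3a fell (-0.54 ± 0.12), 0 rose and 16 of 17 channel genes were not called (0 and 1 over the list alone; adjusted p 0.239 with an estimated correlation). Dissociation-response genes rose in 3 of 17 (Hsp90aa1, Dnajb1 and Socs3), fell in 2 (Jun and Jund) and were not called in 12. List-alone counts were 3 and 2, with an adjusted p of 0.921 with an estimated correlation.

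Of 5 antigen genes 0 were higher and 0 lower in cycling cells, and 0 over the list alone (adjusted p 0.6595 with an estimated correlation). Of 4 non-OPC genes Aldoc fell (-0.77 ± 0.14), 0 rose and 3 were not called. List-alone counts were 0 and 1, with an adjusted p of 0.579 with an estimated correlation. The median of that list was 0.03, while its mean was -0.15 and its camera direction downward.

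At P60, OPC-like cells of white matter (89 cells) and grey matter (121 cells) were compared with 1 library each, no test and counting error only. Among single genes higher in white matter, Meox1 stood at 339 against 76.2 CPM, a ratio of 4.45 (3.15 to 6.38). Ratios were 4.06 (2.88 to 5.80) for the growth cone gene Gap43, 3.36 (2.45 to 4.63) for the lineage factor Sox8, 3.56 (2.62 to 4.89) for the adhesion gene Igsf9b and 20.3 (5.06 to 177; 25 against 2 UMIs) for the amino acid carrier gene Slc38a1. Further genes were Sfxn5 at 6.33 (3.10 to 14.2), Igf2bp3 at 4.87 (2.48 to 10.3), Ccl25 at 5.95 (2.34 to 17.95), Sept1 at 6.17 (2.23 to 21.1) and BC023719, an antisense model, at 4.97 (2.78 to 9.37). Higher in grey matter were Apoe at 9288 against 2232 CPM, a ratio of 4.16 (3.87 to 4.48), the lipid carrier gene Mfsd2a at 7.46 (4.55 to 13.1) and Clu at 5.10 (3.58 to 7.47). So were Npy at 5.95 (3.49 to 10.9), Pmel at 5.59 (3.21 to 10.5) and Abhd3 at 7.18 (3.14 to 20.2). Low counts in white matter left wide intervals for Igfbp2 at 38.2 (6.60 to 1532; 62 against 1 UMI) and Mlf1 at 20.9 (3.51 to 851; 34 against 1).

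The stress genes Fosb at 4.88 (3.52 to 6.93) and Hsp90aa1 at 3.54 (3.10 to 4.05) were higher in grey matter too. Of the 22 measured dissociation-response genes 20 were below 1, white over grey, 0 above and 2 held 1, with a median ratio of 0.280 below all of 10000 matched random lists (percentile 0). In the myelin list 8 of 13 were above, 1 below and 4 held 1 (percentile 100), with Cldn11, Mbp at 5.49 (3.33 to 9.41), Mobp and Mog. Mature oligodendrocyte-like cells were 45.1% of white matter and 1.67% of grey matter, and Mbp lay at 191 CPM in OPC-like and 234 in microglia-like cells of white matter. Pdgfra stood at a ratio of 1.20 (1.06 to 1.35), Olig2 at 1.24 (1.09 to 1.42) and Gpr17 at 0.816 (0.683 to 0.972).

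In the other lists the counts below are members above 1, below 1 and holding 1, white over grey matter, with the percentile in brackets. Antigen presentation gave 0, 5 and 3 (0.01), non-OPC RNA 0, 4 and 1 (0.01, with Cx3cr1 at 0 against 40 UMIs) and imprinted genes 2, 4 and 3 (0.8). Microglia-like cells were 60.5% of grey and 18.7% of white matter. Their median marker in OPC-like cells stood at 3.44% of its microglia-like level in grey and 0.373% in white matter. RNA of microglia-like cells was therefore not excluded as a source of the antigen and non-OPC values. Matrix genes gave 3, 6 and 8 (3.13; Sparcl1 2.85 times higher in grey matter) and kinase inhibitors 1, 2 and 3 (5.88). S phase genes gave 1, 1 and 11 (18.0), differentiation onset 1, 1 and 11 (18.8) and OPC identity 6, 4 and 7 (31.65). Early progenitor genes gave 2, 3 and 10 (37.6), G2M 1, 1 and 12 (39.9) and cholesterol genes 2, 0 and 17 (65.9). Receptors gave 1, 2 and 15 (77.0), patterning 0, 2 and 3 (94.2, although with a median ratio of 1.52) and ion channels 2, 0 and 18 (98.4; Scn2a 2.90, Kcnk2 1.49).

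At P7, OPC-like cells of SVZ (535 cells) and cortex (331) differed in region and strain together, again with 1 library each, no test and counting error only. SVZ cells held more of the histone genes Hist1h1b at 17.3 (12.8 to 24.0), Hist1h4d at 29.9 (16.6 to 60.3), Hist1h2ae at 17.8 (11.02 to 30.8) and Hist1h1e at 12.03 (9.34 to 15.7). Their reads are uncertain because copies are alike and Hist1h1e overlaps Hist1h2be. Trnp1, a regulator of neural progenitors, stood at 22.6 (10.8 to 56.9), Hnrnpa0 at 7.09 (6.18 to 8.17), Pmepa1 at 6.96 (5.57 to 8.80) and the mitochondrial tRNA ligase gene Lars2 at 27.6 (19.5 to 40.5). AY036118, a non-coding model where ribosomal RNA reads can align, stood at 121 (80.8 to 192). Cortex cells held more Pttg1, a securin gene, at 9.50 (7.27 to 12.6), Hddc3 at 9.93 (7.11 to 14.2) and the glycerol phosphate dehydrogenase gene Gpd1 at 4.94 (3.56 to 6.96). They also held more of the elongation factor gene Eef2 at 3.57 (3.39 to 3.77), Gpx3 at 4.21 (3.35 to 5.33), Pnlip at 4.21 (3.13 to 5.71), Rnf121 at 3.70 (2.92 to 4.71) and Matn4 at 3.30 (3.06 to 3.55). Rnf26, which overlaps another gene, stood at 4.13 (3.25 to 5.30) and the antisense model BC023719 at 317 (56.2 to 12581; 186 against 1 UMI).

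Pdgfra stood at 1.03 (0.975 to 1.09), SVZ over cortex. Olig1 at 0.466 (0.450 to 0.482) and Olig2 at 0.479 (0.450 to 0.510) were lower in SVZ, and Cspg4 at 1.27 (1.13 to 1.42), Sox10 at 1.25 (1.13 to 1.39) and Mki67 at 1.75 (1.503 to 2.03) higher. Egfr, a receptor of transit-amplifying cells, stood at 10.8 against 9.20 CPM (1.17, 0.705 to 2.004). Dissociation-response genes were above 1 in 13 of 21, below in 3 and held 1 in 5 (percentile 99.98), led by Fosb at 6.19 (4.92 to 7.89) and Egr1 at 5.36 (4.35 to 6.67). Hspa1a was 8.73 times (4.04 to 21.6) higher in cortex. Glutamate and GABA receptors were above in 11 of 23, below in 3 and held 1 in 9 (99.7; Grik2 2.68). S phase genes gave 12, 1 and 13 (99.3; Hells 2.70), ion channels 8, 1 and 11 (97.1) and kinase inhibitors 2, 1 and 3 (90.5; Cdkn1b 2.64). G2M genes were above in 5, below in 16 and held 1 in 12 (2.54; Ccnb1 0.367, Cdc20 0.473). Non-OPC RNA was above in 3 (the neuronal gene Stmn2, Slc1a2 and Ttr), below in 6 and held 1 in 1 (0; Hbb-bs 57.9 times higher in cortex at 68 against 2 UMIs, 15.4 to 488). Stmn2 stood at 14.3 (9.06 to 24.0), and striatal neuron-like cells were 13.9% of P7 SVZ, so RNA of neurons was not excluded as a source of the higher receptor and channel values.

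The remaining SVZ over cortex lists (above, below, holding 1; percentile) were OPC identity 8, 5 and 4 (87.4), early progenitor 7, 7 and 4 (74.35), matrix 7, 4 and 8 (40.7; Sparcl1 0.248) and differentiation onset 3, 7 and 5 (25.8). Imprinted genes gave 4, 6 and 5 (24.25), cholesterol 5, 9 and 7 (23.6; Acat2 0.333), antigen presentation 1, 4 and 7 (7.76), patterning 1, 3 and 6 (5.5) and myelin 1, 5 and 6 (2.8). In P7 SVZ 33.4% of barcodes were left out for mitochondrial RNA, and 78.9% of its OPC-like cells lay in cluster 27.

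**Figure D5:**
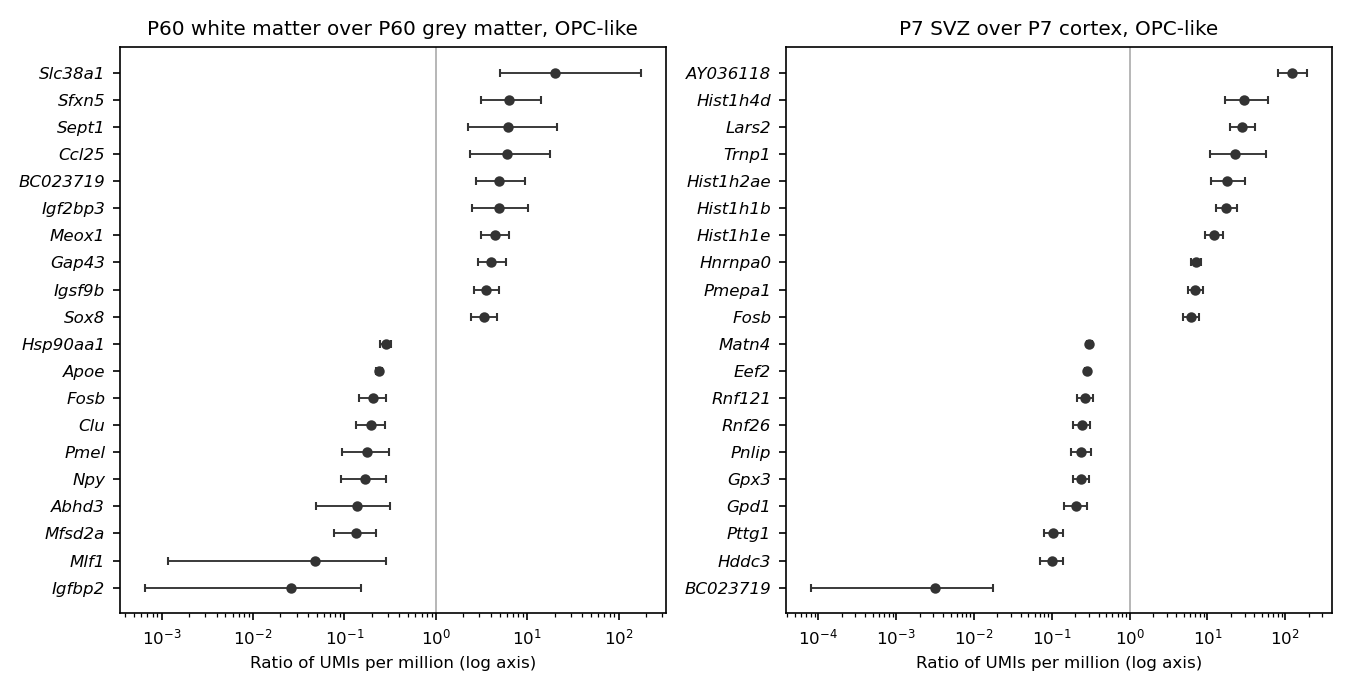
Ratios of named genes in OPC-like cells with exact 95% intervals, counting error only. Meox1 was 4.45 times higher in P60 white than grey matter, and Pttg1 9.50 times higher in P7 cortex than SVZ.

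In other classes few genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and genes from counts of 5 or fewer are named after their values were seen. Adult astrocyte-like cells (10690.0 genes, n = 4 and 3) had 11 genes higher and 4 lower (19 and 13 with RLE size factors). Higher were the matrix genes Prelp (5.10 ± 0.64; 2.64 to 106 CPM) and Efemp1 (4.18 ± 0.65), the NMDA receptor gene Grin2b (2.94 ± 0.36; 10.95 to 85.6), the Wnt secretion gene Wls (2.58 ± 0.36) and the antisense model Rab26os (2.90 ± 0.45). Lower were Rnd1 (-3.38 ± 0.51; 21.6 to 1.68) and the Y-linked Eif2s3y, Uty and Ddx3y. Microglia-like cells (9659 genes, n = 4 and 3) had Dcpp2 higher (0.391 to 19.8 CPM) and Eif2s3y, Uty and Ddx3y lower. COP-like cells (9200.0 genes, n = 4 and 2) had Xist higher and Eif2s3y lower. Neuroblast-like cells (8966 genes, n = 4 and 2) had 0 higher, and Eif2s3y and Ddx3y lower, by edgeR's quasi-likelihood test. Unadjusted p under 0.05 were found for 2817 astrocyte-like, 1289 microglia-like, 1087 COP-like and 514 neuroblast-like genes.

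Without P15 cortex the counts, higher and lower, were 1368 and 1295 in astrocyte-like, 259 and 405 in microglia-like, 56 and 27 in COP-like and 2 and 2 in neuroblast-like cells. Astrocyte-like counts were 3 and 3 without P2 cortex, 1 and 2 without P7 cortex, 6 and 4 without P7 SVZ and 0 and 0 without any 1 of the 3 adult libraries. Microglia-like counts were 4 and 2 without P60 cortex and 0 and 2 without any 1 of the other 5. COP-like counts were 0 and 2 without P2 cortex, 0 and 1 without P7 SVZ and 0 and 0 without P7 cortex, P60 cortex or white matter. Neuroblast-like counts were 0 and 0 without the same 3. With no filter on low counts they were 293 and 496, 77 and 199, 107 and 114, and 43 and 92 in astrocyte-like, microglia-like, COP-like and neuroblast-like cells.

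The genes called in OPC-like cells moved in the same direction elsewhere in 458 of 481 tested in COP-like cells (95.2%), 440 of 501 in astrocyte-like cells (87.8%), 441 of 489 in microglia-like cells (90.2%) and 367 of 486 in neuroblast-like cells (75.5%). Among the genes not called in OPC-like cells the same direction was found in 66.2, 62.6, 65.4 and 64.4%. The classes come from the same 7 libraries, so these shares do not tell a change in each class from one common to whole libraries. Called the same way in both were 2, 6, 3 and 2 genes. In astrocyte-like cells these were 3 higher and 3 lower where independent calls would give 0.183 and 0.117, and in microglia-like cells 3 lower where they would give 0.114, all of these Y-linked. The astrocyte-like and OPC-like changes of Sparcl1, Apoe, Hapln1, Gjc3, Gstt1 and Ifi27 differed in tests of the difference given in the closing part. The other named and marker genes did not pass there, and against microglia-like cells none passed.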

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

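The tests of sex and of handling in their present wording, and the count of genes that could not be tested in cells without cycle UMIs, were chosen after the result was seen, and the handling test would have read as excluded in its earlier wording.

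The stage calls in OPC-like cells could reflect a change of whole libraries, a loss of dividing cells or the sex of the animals. In microglia-like cells the same genes kept a median of 0.587 (0.525 to 0.659, 489 genes) of their OPC-like log2 fold change, and in astrocyte-like cells 0.784 (0.701 to 0.833), so a shared change with stage or library may be part of the calls. The calls that could be tested in cells with 0 cycle-list UMIs kept a median of 0.977 (0.955 to 0.991) of their change there. Of these 443 genes 438 had the same sign, so their change was also present outside the cycling calls. Only 1 of them was on the cycle lists, and 210 others (97 higher, 113 lower, 32 on the cycle lists) had too few UMIs there. Genes expressed mainly in dividing cells drop out of this test, so it cannot decide for them. Genes on chromosome X or Y were 3.68% of the calls (24 of 653) and 3.52% of the tested genes, but with Y-linked genes at 128, 127, 115 and 165 CPM in the whole early libraries and 1, 1 and 0 UMIs in the adult ones, sex stays open. Of the 35 splits of the libraries, 2 gave as many OPC-like genes (653 for the real split, 858 for P2 cortex, P7 cortex and P7 SVZ against the rest). The split with 858 also follows age, with P15 cortex on the adult side, and parted more genes than the real one. With 2 of 35 splits, chance cannot be excluded.

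Microglial genes such as C1qa in adult OPC-like sums could be RNA from microglia-like cells in droplets of other cells. The markers stood at a median of 0.843 (P60 cortex), 1.29 (grey matter) and 0.622 (white matter) times their level in astrocyte-like cells, which is consistent with a shared background. In OPC-like cells the median marker reached 0.752, 3.44 and 0.373% of its microglia-like level, and the highest single marker 25.4%. Expression in the OPC-like cells themselves stays open.

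Dissociation-response genes were higher in OPC-like cells of P60 grey matter than white matter in 20 of 22, and handling of that library is a candidate explanation. In astrocyte-like cells 11 of 16 were also higher in grey matter (percentile 100 of matched random lists), but in microglia-like cells 10 were above and 10 below of 23 (percentile 29.4). Hspa1a was 6.43, 6.53 and 1.72 times higher in OPC-like, astrocyte-like and microglia-like cells of grey matter, and Fos 3.03, 4.27 and 0.514 times. The classes differ, so the test decides neither way, and a difference between regions stays open.

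In astrocyte-like cells 2 of the 35 splits gave as many genes as the real 15, the highest other 2874, and in microglia-like cells 2 gave as many as the real 4, the highest other 900, so chance cannot be excluded. Both highest splits set P2 cortex, P7 cortex and P7 SVZ against P15 cortex and the adult libraries, which points to a structure of the samples. For cycling against non-cycling OPC-like cells 16 swaps were possible and 1, the real one, gave as many (1613, highest other 913), too few for a share under 0.05.

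P15 cortex stood apart among the early libraries in 4 of 40 groups of values, where chance alone gives about 1 in 20: a mature share of the lineage of 18.4% (others 0 to 0.402), Gjc3 at 55.1 CPM (6.38 to 11.5), Tmem59l at 33.1 CPM (4.56 to 9.23) and Rbm3 at 349.7 CPM (618 to 671). The stage change in OPC-like minus astrocyte-like cells, as log2 difference ± SE with adjusted p, was 3.25 ± 0.48 (0.0118) for Sparcl1, 3.39 ± 0.57 (0.0155) for Gjc3, 3.39 ± 0.47 (0.00910) for Apoe, 2.59 ± 0.51 (0.0265) for Gstt1, 4.07 ± 0.41 (0.00119) for Hapln1 and 1.93 ± 0.32 (0.0155) for Ifi27, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other named and marker genes did not pass. Against microglia-like cells none passed by the same test, the lowest adjusted p being 0.104 (Ifi27) and 0.134 (Apoe). These 6 genes had been picked for a large stage change in OPC-like cells of the same libraries.

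As lists against astrocyte-like cells, median differences (camera adjusted p, then adjusted p with an estimated correlation) were 0.93 (0.00479, 0.343) for early progenitor genes, 0.97 (0.0369, 0.343) for OPC identity, -0.72 (0.00120, 0.497) for cholesterol synthesis, 2.47 (1.3e-05, 0.254) for matrix, 3.03 (2.6e-16, 0.254) for dissociation-response, 1.99 (0.0434, 0.254) for kinase inhibitors and -0.61 (0.0497, 0.254) for patterning genes. Against microglia-like cells they were 1.31 (0.00309, 0.926) for G2M, 0.58 (0.00309, 0.644) for OPC identity, 1.40 (3.1e-06, 0.387) for matrix and 1.27 (0.0423, 0.387) for kinase inhibitors. In the 290 unnamed cells of P60 grey matter the cytokine genes Tnf and Ccl3 stood at 1549.9 (1450 to 1655) and 7290.0 (7070 to 7515) CPM, and 8.44% (7.30 to 9.70) of the 2132 P7 SVZ barcodes over the mitochondrial limit, with a median of 2564 UMIs, held a Pdgfra UMI.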

How the results depend on the processing

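The estimated list correlation, the list tests under other settings, the other-class alternatives, the test of genes past the 0.5 limit and leaving out P7 SVZ with P60 grey matter were chosen after results were seen. The cause of the differences below was not tested. No paired analysis was possible because replicate numbers follow only the order of the labels, and nothing links an early to an adult library. For OPC-like genes higher in adult (308) and OPC-like genes lower in adult (345), counts were 615 and 623 with no filter on low counts, 132 and 133 with clusters made per library, 115 and 144 with the marker gate and 72 and 103 in cells with 0 cycle-list UMIs. Without P7 SVZ and P60 grey matter they were 18 and 19, of which 35 were among the 653. Leaving out 1 library gave 8 to 614 higher and 7 to 591 lower, least without P60 grey matter and most without P15 cortex. RLE size factors (315 and 347), DESeq2 (389 and 415), doublets kept (258 and 331), 1000 genes per cell (275 and 325), a mitochondrial limit of 20% (303 and 357), equal cell numbers (283 and 332) and only genes past the 0.5 limit (285 and 334) moved them by under 1.5 times. All 653 genes kept their sign wherever they were tested, except 1 of 647 with the gate and 5 of 443 in cells with 0 cycle-list UMIs. These settings reuse the libraries in which the genes were called, so a kept sign is no separate evidence. Without P60 grey matter 15 of the 653 were still called.

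Of the list tests (12 of 16), 0 passed with an estimated correlation, 7 in cells with 0 cycle-list UMIs, 12 without P7 SVZ and P60 grey matter, and 10 to 11 with 1 library left out. The sign of an uncalled gene turned: Mbp (-0.09) was 2.0e-04 with doublets kept, 0.10 with equal cell numbers, 0.83 without P15 cortex, 0.16 without P60 cortex, 0.33 without P60 grey matter and 0.080 without P7 SVZ and P60 grey matter, a range of -1.11 to 0.83 over single libraries left out. Over all settings 511 of the reported stage values were the same in sign and call, 59 lost the call and 6 turned. For genes higher in cycling OPC-like cells (930) and genes lower in cycling OPC-like cells (683), counts were 442 and 157 with DESeq2, 543 and 426 at 2 or more UMIs, 218 and 6 with no library block, 208 and 105 on thinned sums, and 603 to 1064 and 363 to 734 with 1 library left out. RLE (923 and 703) and no filter (1184 and 599) moved them by under 1.5 times, and 184 named values were the same and 11 lost the call.

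In the other classes no filter on low counts gave 107 and 114 (COP-like), 293 and 496 (astrocyte-like), 43 and 92 (neuroblast-like) and 77 and 199 (microglia-like), and RLE gave 19 and 13 in astrocyte-like cells. With 1 library left out the ranges were 0 to 56 and 0 to 27 (COP-like), 0 to 1368 and 0 to 1295 (astrocyte-like), 0 to 2 and 0 to 2 (neuroblast-like) and 0 to 259 and 2 to 405 (microglia-like). The share differences ranged, with 1 library left out, from -8.50 to -4.45 points (OPC-like), 39.9 to 73.8 (mature share) and -20.6 to -16.1 (cycling), and kept their sign in every setting run. The named genes of both pairs, 20 and 20, kept their direction with doublets kept and with clusters made per library.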

Other observations

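Cycling calls in microglia-like cells were most frequent in the P7 libraries, among the 6 libraries with at least 20 such cells of enough depth (P2 cortex had fewer). They were made in 54.0% in P7 cortex and 37.1% in P7 SVZ, with Mki67 at 127 and 184 CPM, against 2.19% at P15 and 2.68% in P60 cortex with 0 Mki67 UMIs. In P60 white matter the share was 6.15%, with Mki67 at 5.58 CPM. In grey matter, where microglia-like cells had such calls in 21.2% at 1.39 Mki67 CPM, the calls say little.

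The 2 tests below were planned before their results were seen. Whether P15 OPC-like cells lie between the younger and the adult libraries was tested on the 1205 genes called without P15 cortex. Their median position was 0.491 (0.469 to 0.508) on a scale from the younger libraries to the adult ones, 0.597 for 614 higher and 0.358 for 591 lower genes, and 91.95% lay between. A library with no part in the difference would also lie near 0.5 by symmetry, which was seen only after the result, so this position does not decide whether P15 cells lie between the younger and the adult ones.

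A further hypothesis was that early progenitor genes and receptor or channel genes mark opposite ends of 1 axis among the OPC-like cells of each library. In 0 of 7 libraries was the correlation below the 2.5th percentile of matched random list pairs, the lowest being percentile 18.6 in P60 grey matter. In 6 of 7 it was at or above 0 (-0.14 to 0.32), so opposite ends of one axis within each library were not found here. Only 30 (P60 white matter) to 217 (P15 cortex) cells per library entered. They held a median of 4 to 7 receptor and channel UMIs each, so a weak opposite trend could be missed.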
